A study of Bombyx mori with 3 samples.

How the data were processed

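Larvae of the silkworm Bombyx mori, strain P50, were fed mulberry leaves that had been dipped for 1 min in phoxim, an organophosphate insecticide, at 4 µg/mL or in water, per the labels' protocols. Feeding began on day 3 of the fifth larval stage, the midguts were dissected 24 h later, and 30 larvae were used per experiment. Each of 3 two-colour arrays carried RNA of phoxim-treated midguts in 1 channel and RNA of control midguts in the other. The series design calls the 3 arrays biological replicates. The number of arrays limits the precision.

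The deposited files give, per spot, a Cy5 and a Cy3 intensity on a linear scale and a ratio of phoxim over control, per the file headers. The intensities hold no separate background, and many Cy5 values are 0, so they were taken as background-subtracted. The deposited ratio is not the plain quotient of the intensities: the difference is smooth in intensity and varies by block, as after an intensity-dependent normalization within the array. The scanner, the software and the normalization method are not given in the sources used here. The deposited value table of the series holds log2 values that equal the log2 of the deposited ratio to within 4.9e-09 on all 24288 spots. Its column medians were 0.040, -0.021 and 0.016 for replicates 1, 2 and 3. Its scale and centring are therefore those of the deposited ratio, and its direction is the one the headers state.

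The sources disagree on the dyes of replicate 2. The labels and the series design put phoxim in Cy5 on all arrays, without dye swaps. The header of replicate 2 names the control RNA for Cy5 and the phoxim RNA for Cy3, and states its ratio as phoxim over control. The headers were followed, so that phoxim was in Cy5 on replicates 1 and 3 and in Cy3 on replicate 2. The other direction was run as an alternative chosen after seeing the data.

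The planned values were normexp-corrected foreground and background intensities with loess. Separate backgrounds were not in the files used here, so the deposited ratio was used as it stood, which the plan allowed for a ratio already corrected and normalized. The array has 23229 gene probes with 1 spot each, 677 positive control spots and 382 negative control spots in 48 blocks. Control spots were left out of the tests. A flag marks spots whose brighter channel reached 400, and a second level marks 1500. Both levels were checked against the intensities on each array. A probe was kept if it carried either mark on all 3 arrays, which left 3964 probes of 3890 genes. Kept probes had no intensity at 0. Median intensities of the kept probes ranged from 1074.5 to 1272 for phoxim and from 1123.5 to 1159 for control. Repeated spots of 5 control probes varied within an array with SDs of 0.084 to 0.20 on the log2 scale.

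The log2 ratio was fitted with an intercept in limma 3.58.1 under R 4.3.3, with moderated variances (eBayes, no trend), two-sided, and Benjamini-Hochberg adjustment over the kept probes. The threshold was an adjusted p of 0.05. Gene lists were tested with camera from limma with a preset inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over the 23 lists that had at least 3 measured genes. Camera sets the members of a list against all other kept genes, so a list called higher or lower is so relative to those genes. The 25 lists were patterns on gene symbols and descriptions. A gene was represented by its brightest kept probe. Probes sharing a gene identifier were treated as 1 gene; this grouping replaced the array's own gene models after list results had been seen, and the earlier grouping is among the alternatives.

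Names came from the files. Of the gene probes, 1415 had a symbol, 1316 a gene identifier, and 1237 of these matched the reference table of assembly ASM3026992v2, which was used for names only. For 11243 probes the symbol or the best protein match said what the gene is. Best matches are to proteins of other species for many probes, so such names are by similarity. Probes without a symbol are given by their array identifier. No coordinates are given because no genome was used.

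The genes named in the text follow a rule fixed with the lists before the data were examined. It takes up to 10 named genes with the highest and the lowest mean log2 ratio among those past the threshold with 1 sign on all arrays. It adds, in each list with at least 3 measured genes, the member with the smallest adjusted p in each direction, or the smallest p if none passed. It also takes every measured acetylcholinesterase gene. Other genes are named where the text says so.

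A spot below the 95th percentile of the negative controls of its channel on every array of a group has only a bound there, computed from channel values after adding 50, loess and Aquantile normalization, and open to dye bias. A spot at 99% or more of the highest intensity on its array was taken as saturated, since the files flag no saturation; its bound is the lower of the fold from the same channel values and the fold of the deposited ratio. The fit was tested on simulated data: the 3964 probes received the measured variances, and 200 of them received known changes. Of those changed by 2-fold, 53.7% were recovered, of those by 4-fold 85.1%, and of those by 8-fold 93.9%. Of 160 calls, 5 were false. The measured data gave 27 calls, and the adjusted threshold loosens as more probes change, so the shares recovered may be too high for the measured data. For the gene list comparison, simulated on the same 3964 probes, a list of 30 shifted by 0.5 on the log2 scale was called. Of 20 unshifted lists, 0 were called. Lists as small as the 4 UDP-glycosyltransferase genes, or means as small as the ribosomal -0.06, were not simulated. In both simulations the noise was drawn for each probe independently of the others. They therefore cannot show how often probes or lists are called falsely where genes vary together. In the measured data 0 lists were called with an estimated correlation.

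Alternatives covered the background, the normalization within and between arrays, the filter on dim probes, the variance model, a test against 1.5-fold, the probe chosen per gene, the inter-gene correlation, the dyes and each replicate left out. Members judged not to belong to their lists were left out by name in an alternative, and ribosomal proteins named as mitochondrial in another. These 2 alternatives were chosen after the ratios had been seen.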

Results

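The series asked how the midgut of silkworm larvae responds to phoxim, an organophosphate insecticide that inhibits acetylcholinesterase. RNA from phoxim-treated and control midguts was compared directly on 3 two-colour arrays, 1 pair of RNAs per array. Of 23229 gene probes, 4494 were above the flag level on replicate 1, 4714 on replicate 2 and 4343 on replicate 3. The 3964 probes above it on all 3 arrays were tested. All directions below are phoxim over control as the array headers state them; for replicate 2 the labels name the opposite dyes, and the turned direction gave 0 calls in limma, with 29 probes at an unadjusted p below 0.05.

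Transcripts of haemolymph storage and 30K proteins had the 10 highest ratios among the probes that rose after phoxim. The 30K lipoproteins are abundant small haemolymph proteins made by the larval fat body, and the arylphorins are its amino acid storage proteins. These families were grouped after their values were seen: of their 14 measured genes, 9 rose, by 4.09-fold to 8.05-fold, and 5 did not pass. In total 27 probes passed the threshold, 20 higher and 7 lower, and all 27 changed at least 2-fold with 1 sign on all 3 arrays.

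Among the 30K genes, sw01299 had a mean log2 ratio of 3.01 ± 0.81 (SD, n = 3, adjusted p = 0.012, limma). The files assign this probe to 2 genes, and its best protein match is a 30K protein. The probe sw19103 reached 2.66 ± 0.45 (SD, n = 3, adjusted p = 0.0068, limma) and is likewise assigned to 2 genes, both 30K lipoproteins. LP3 and Lp-c6, further 30K proteins, had mean log2 ratios of 2.47 ± 0.76 and 2.41 ± 0.67 (SD, n = 3). The 30K probes sw22574, sw03882 and sw19281 gave 2.67, 2.11 and 2.03. The control channel was above the negative controls on 2 arrays for sw22574 and on 1 for sw03882, so their ratios are partly bounds. The arylphorin-like probe sw06703 gave 2.67 ± 0.47, and Sp2, an arylphorin, 2.06 ± 0.54 (SD, n = 3). Sequences of the 30K family are similar to one another, and cross-hybridisation between them was not tested. The 30K probes sw22699 and sw22776 belong to 1 gene model and disagreed: the brighter sw22699 had a mean of -0.03 and sw22776 one of 2.05. Sp1, the sex-specific storage protein, did not pass (adjusted p = 0.38, limma), with log2 ratios of 4.53, 1.70 and -0.96 on replicates 1, 2 and 3 and a control above the negative controls on 2 of them.

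**Figure D1:**
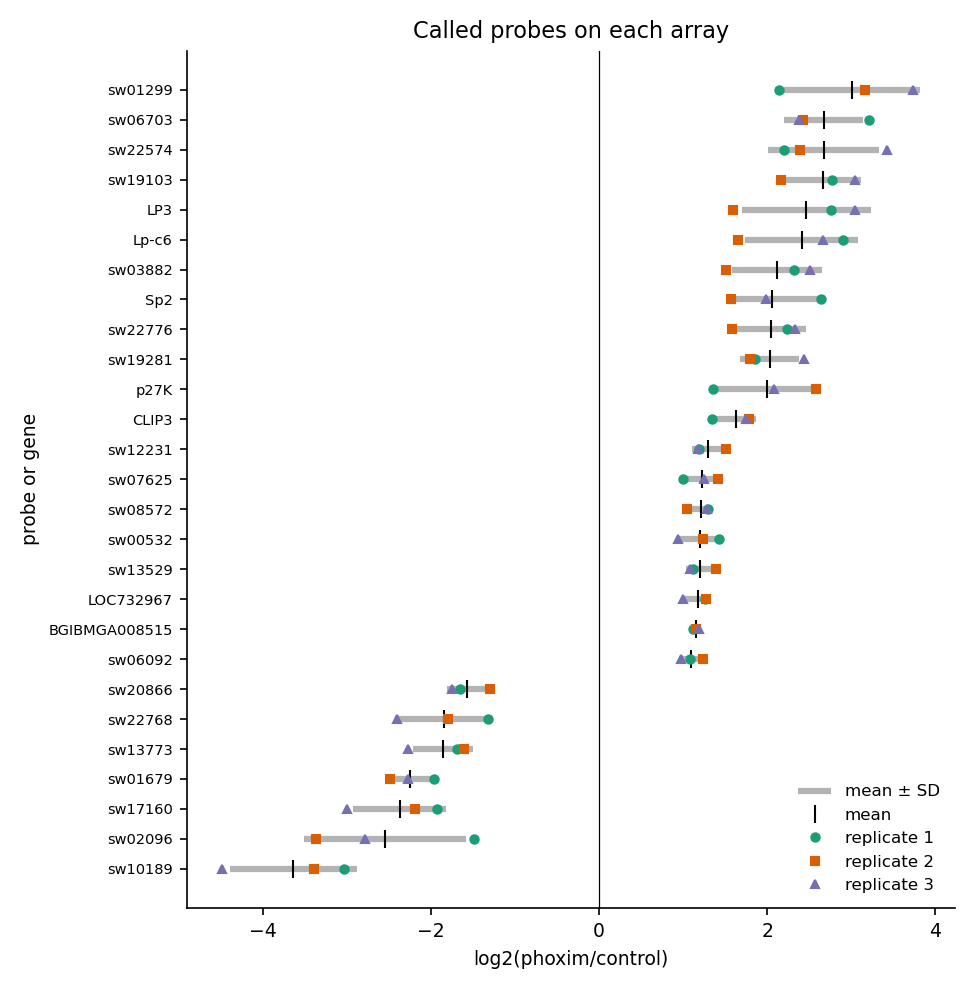
Log2(phoxim/control) of the 27 called probes on each of the 3 arrays (symbols), with the mean (tick) and SD (grey bar). Storage and 30K proteins occupy the top of the plot, with means up to 3.01. For sw10189, at the bottom, the plotted ratios are not measured values, and it was at least 2.77-fold lower.

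Outside these families, p27K rose by 2.00 ± 0.62 on the log2 scale (SD, n = 3, adjusted p = 0.026, limma). CLIP3, a serine protease matched to a haemocyte protease, rose by 1.63 ± 0.25 (SD, n = 3, adjusted p = 0.014, limma), its control being above the negative controls on 2 arrays. The lipase probe sw13529 was at least 2.29-fold higher (adjusted p = 0.033, limma), its phoxim channel being saturated on all 3 arrays. Further called genes, named after their values were seen, were sw12231 at 1.29 and sw07625, matched to the nuclear receptor E75, at 1.22. The best match of sw12231 is a carbonic anhydrase of the bacterium Vibrio fischeri. A separate probe of E75, an early ecdysone response gene, had a mean of 0.79 and did not pass (adjusted p = 0.14, limma).

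Among the probes that fell, the putative alcohol dehydrogenase probe sw01679 had a mean log2 ratio of -2.24 ± 0.26 (SD, n = 3, adjusted p = 0.0068, limma). The trypsin probe sw02096 had one of -2.55 ± 0.96 (SD, n = 3, adjusted p = 0.032, limma). The probe sw20866, matched to an acyl-CoA desaturase, an enzyme that places double bonds in fatty acids, had one of -1.57 ± 0.24 (SD, n = 3, adjusted p = 0.014, limma), its phoxim channel being above the negative controls on 2 arrays. The best match of the probe sw10189 is a bacterial IS1 transposase. It was not above the negative controls in the phoxim channel of any array and was at least 2.77-fold lower. Its call (adjusted p = 0.0068, limma) rests on the deposited ratios and does not test this bound. Of the 27 called probes, 5 had no informative name, 2 of them higher and 3 lower.

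**Figure D2:**
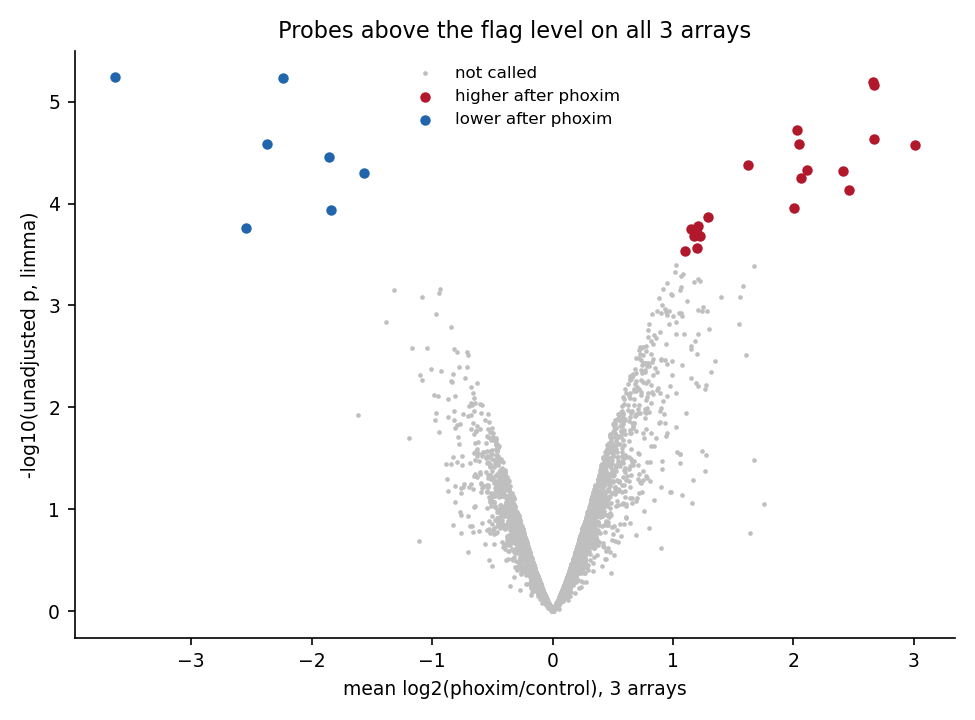
Mean log2(phoxim/control) over 3 arrays against -log10 of the unadjusted p from limma, 1 point per kept probe. The 20 called probes higher after phoxim are red and the 7 lower are blue.

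Markers of fat body, muscle and haemocytes, which border the midgut epithelium, were higher as groups. These lists were drawn by name and held members later judged not to belong. Without those members the means were 1.66, 0.58 and 0.72 for fat body, muscle and haemocytes, and the lists still passed in camera. Of 24 measured fat body marker genes, 9 rose and 15 did not pass, and 11 rose adjusted over the list alone. All 9 are storage and 30K genes named above. The list mean was 1.12 and its median 0.64 (adjusted p = 1.2e-08, camera; adjusted p = 0.65 with an estimated correlation). A set of 16 other genes listed as fat body or haemolymph, after the results were seen, had a median of 0.076. Its members ranged from -0.50 (sw01309) to 1.60 (Sci-sb), and their expression in fat body was not tested. Of 18 muscle genes, 0 passed over all probes and 7 rose adjusted over the list alone; the mean was 0.53 (adjusted p = 1.1e-04, camera; adjusted p = 0.65 with an estimated correlation). MLC-2, myosin light chain 2, had a mean of 0.89 ± 0.04 (SD, n = 3, adjusted p = 0.068, limma). Of 7 haemocyte genes, CLIP3 rose and 6 did not pass, and 2 rose adjusted over the list alone; the mean was 0.56 (adjusted p = 0.023, camera; adjusted p = 0.65 with an estimated correlation). With the array's own gene models the haemocyte list did not pass (adjusted p = 0.054, camera), nor with both channels above the flag level or all probes kept, where the mean was 0.17 and 0.16. The 7 cuticle and tracheal genes had a mean of 0.23 (adjusted p = 0.44, camera), or 0.09 to 0.49 with 1 replicate left out, with CPR46, a cuticle protein, at 0.73 ± 0.87 (SD, n = 3). The 5 nerve and neuropeptide genes had a mean of 0.16 (adjusted p = 0.45, camera), with the tachykinin receptor probe sw11294 at 0.57 ± 0.29 (SD, n = 3). No silk gland marker was above the flag level on all arrays.

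Digestive proteases shifted in both directions. Of 34 measured serine protease genes, 3 rose, 1 fell and 30 did not pass. Adjusted over the list alone, 12 rose and 3 fell. The list was drawn by name and also held sw11925, an antitrypsin precursor (-0.07), and CLIP11, a masquerade-like serine proteinase homolog (0.61). The gene sw11925 is also among the 16 other fat body or haemolymph genes above. With members judged not to belong left out, the list mean stayed at 0.23. The list mean was 0.23 (adjusted p = 0.023, camera, or adjusted p = 0.65 with an estimated correlation). It fell to 0.10 and did not pass with plain subtraction and loess. In the same samples fat body markers, of which only storage and 30K genes passed, had a mean of 1.12 and a median of 0.64. LOC732967, a chymotrypsin-like protease, rose by 1.18 ± 0.15 (SD, n = 3, adjusted p = 0.033, limma), and the alkaline trypsin probe sw00532 and chymotrypsin probe sw06092, named after their values were seen, rose by 1.20 and 1.10. Of 49 other digestive peptidases, lipases and carbohydrases, the lipase sw13529 alone passed, and the list did not (adjusted p = 0.87, camera); 2 rose adjusted over the list alone. The 11 peritrophic membrane and chitin genes had a mean of 0.48 (adjusted p = 0.057, camera) and passed in some alternatives, 2 rising adjusted over the list alone. Their medians were 1.10, 0.30 and 0.00389 on replicates 1, 2 and 3, and the chitin synthase probe sw11665 had 0.88 ± 0.52 (SD, n = 3). The 8 nutrient transporters had a mean of 0.02 (adjusted p = 0.99, camera), with the amino acid transporter probe sw19553 at -0.81 ± 0.63 (SD, n = 3).

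Of the lists drawn by name for detoxification, the modification or export of foreign compounds, UDP-glycosyltransferases alone passed in the main setting. Their 4 measured genes had a mean of 0.84 (adjusted p = 0.023, camera; adjusted p = 0.70 with an estimated correlation), while fat body, haemocyte and muscle markers were higher by 1.12, 0.56 and 0.53 in the same samples. With all probes kept the mean was 0.14 and the list did not pass (adjusted p = 0.58, camera). None of the 4 passed over all probes, and 3 rose adjusted over the list alone. The probe sw21445, matched to a UDP-glucuronosyltransferase, had a mean of 1.22 ± 0.40 (SD, n = 3, adjusted p = 0.066, limma). The highest mean of the 4 was that of sw19839 (1.58), which is also in the hormone response list below. The 14 cytochrome P450 genes had a mean of 0.27 (adjusted p = 0.075, camera) and passed in some alternatives. The mean was 0.17 to 0.34 with 1 replicate left out, and the CYP9A-like probe sw20566 had 0.64 ± 0.35 (SD, n = 3). The 12 glutathione S-transferases averaged 0.10 (adjusted p = 0.77, camera), or 0.02 to 0.21 with 1 replicate left out, with GSTd2 at 0.52 ± 0.26 (SD, n = 3). The 6 ABC transporter genes averaged 0.20 (adjusted p = 0.44, camera), or 0.11 to 0.26 with 1 replicate left out. LOC732866, a member of subfamily F, had 0.42 ± 0.31 (SD, n = 3). The names do not show that these 6 genes export foreign compounds. The 23 carboxylesterases had a mean of 0.07, a median of -0.03 and a test direction of lower (adjusted p = 0.72, camera), so that these differed in sign. Their mean was 0.02 to 0.15 with 1 replicate left out, and the esterase probe sw11948 had 1.20 ± 0.68 (SD, n = 3). No member of these last 4 families passed, over all probes or adjusted over the list alone.

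Acetylcholinesterase, the enzyme phoxim inhibits, could not be compared. All 4 of its probes were below the flag level on at least 2 arrays, with intensities of 0 to 530, and none was kept. Of all 21 probes of cholinergic genes on the array, 0 were kept.

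**Figure D3:**
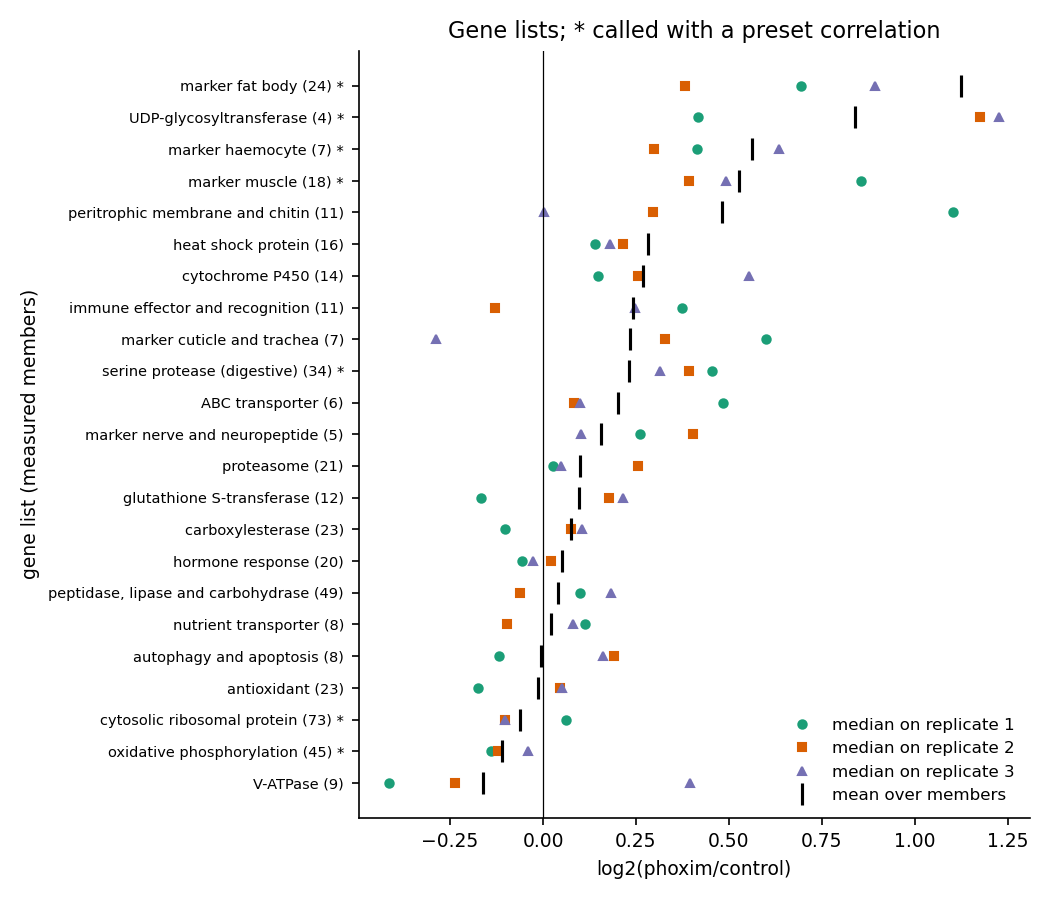
Gene lists with at least 3 measured genes, by mean log2(phoxim/control) over members (tick) and by the median on each array (symbols); the number of measured members is in parentheses. Asterisks mark the 7 lists called with a preset correlation, from fat body markers at 1.12 to oxidative phosphorylation at -0.11; with an estimated correlation 0 were called.

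Stress and immune lists did not pass. The 16 heat shock protein genes had a mean of 0.28 (adjusted p = 0.17, camera), 2 of them rising adjusted over the list alone, with LOC778468 at 0.94 ± 0.26 (SD, n = 3, adjusted p = 0.075, limma). The 11 immune genes had a mean of 0.24 (adjusted p = 0.44, camera), 3 of them rising adjusted over the list alone, with the peptidoglycan recognition protein probe sw22599 at 1.06 ± 0.39 (SD, n = 3). The 23 antioxidant genes averaged -0.01 (adjusted p = 0.45, camera), or -0.12 to 0.10 with 1 replicate left out, with the copper chaperone probe sw02910 at 0.45 ± 0.13 (SD, n = 3). The 21 proteasome genes averaged 0.10 (adjusted p = 0.45, camera), or 0.05 to 0.13 with 1 replicate left out, with sw06058 at 0.32 ± 0.26 (SD, n = 3). The 8 autophagy and apoptosis genes had a mean of -0.01 and a median of 0.12, which differ in sign (adjusted p = 0.90, camera). Their mean was -0.09 to 0.09 with 1 replicate left out, and sw01943 had -0.47 ± 0.49 (SD, n = 3). The 20 hormone response genes had a mean of 0.05, a median of -0.04 and a test direction of lower (adjusted p = 0.87, camera). Their mean was -0.02 to 0.14 with 1 replicate left out, and 4 rose and 2 fell adjusted over the list alone. Their smallest p belonged to sw19839, matched to a viral ecdysteroid UDP-glucosyltransferase, at 1.58 ± 0.68 (SD, n = 3, adjusted p = 0.067, limma). It is also among the 4 UDP-glycosyltransferase genes above. The called probe sw07625, matched to E75 (1.22), is not among the 20 hormone response genes, so the list does not cover every such gene.

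Oxidative phosphorylation and ribosomal protein genes were lower as lists, by amounts that depended on the normalization, while fat body and muscle markers were higher by 1.12 and 0.53 in the same samples. The 45 oxidative phosphorylation genes, which encode the mitochondrial respiratory chain, had a mean of -0.11 (adjusted p = 0.013, camera; adjusted p = 0.65 with an estimated correlation). The ATP synthase gene LOC733114 had -0.81 ± 0.48 (SD, n = 3, adjusted p = 0.16, limma). The 73 ribosomal protein genes, 3 of them mitochondrial by name, had a mean of -0.06 (adjusted p = 0.023, camera; adjusted p = 0.88 with an estimated correlation), a median of 0.06 on replicate 1 and RpL7Ae at -0.52 ± 0.11 (SD, n = 3). Without the 3 the mean was -0.053 (adjusted p = 0.044, camera), chosen after seeing the data. The files' own ribosome term, of 56 genes, did not pass, with a mean of -0.02 (adjusted p = 0.37, camera). No member of either list passed, also adjusted over the list alone. With plain subtraction and loess on the intensities the 2 means were -0.24 and -0.21, and with median centring -0.044 and -0.0042. Both lists passed with median centring (adjusted p = 0.0025, camera), where the ribosomal mean was close to no change. The 9 V-ATPase genes, which encode the proton pump of midgut goblet cells, had a mean of -0.16 (adjusted p = 0.28, camera). The list passed in some alternatives, as with plain subtraction and loess (-0.35), and its mean turned to 0.06 without replicate 1. The gene LOC733031 had -0.45 ± 0.46 (SD, n = 3).

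The count of called probes depended on single arrays and settings: it was 4 without replicate 2 and 470 without replicate 3, 1 with scaling between arrays (600 at an unadjusted p below 0.05, 603 in the main setting), 9 in a test against 1.5-fold and 16 with both channels above the flag level. It was 0 with a term for dye orientation (348 at an unadjusted p below 0.05) and 0 with all probes kept (450 at an unadjusted p below 0.05), both in limma. Of the 7 called lists, fat body and muscle markers alone passed without each of the 3 replicates in turn. Across kept probes, which are not independent replicates, log2 ratios of replicates 1 and 2 correlated with r = 0.62, those of replicates 1 and 3 with r = 0.18 and those of replicates 2 and 3 with r = 0.26. Over all gene probes, most of them dim, the same values were -0.47, 0.42 and -0.45.

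**Figure D4:**
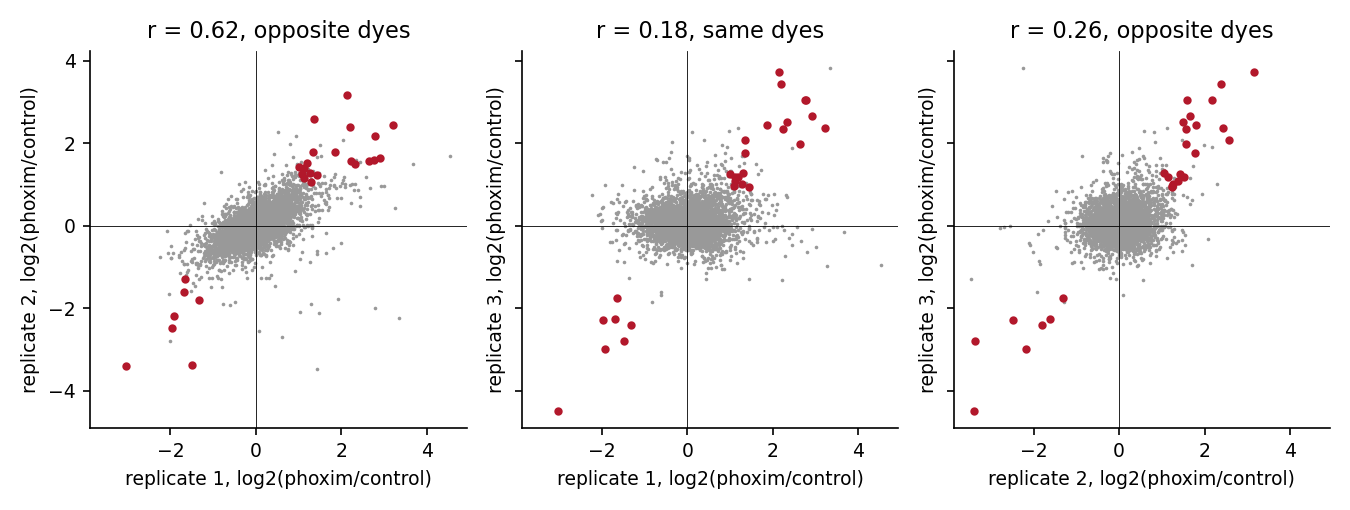
Log2(phoxim/control) of each kept probe on 1 array against another, with the 27 called probes in red. Replicates 1 and 2, with opposite dyes, had r = 0.62, replicates 1 and 3 r = 0.18 and replicates 2 and 3 r = 0.26.

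Positive control spots changed sign with the dye orientation stated in the array headers. Each of the 8 controls Y1 to Y8, spotted 48 times, had a sign of log2(Cy5/Cy3) on replicate 2 opposite to that on replicates 1 and 3; for Y6 the medians were -4.01, 4.84 and -4.38 on replicates 1, 2 and 3.

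**Figure D5:**
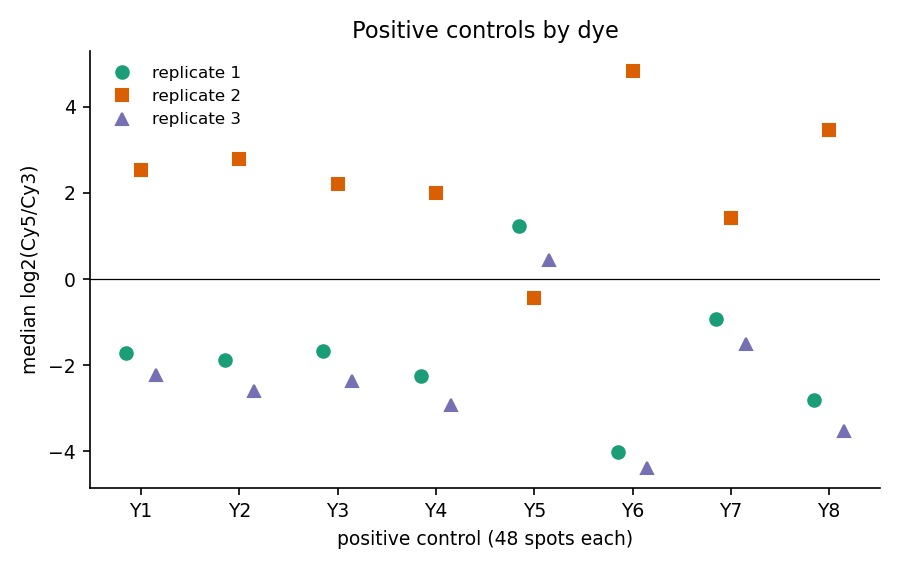
Median log2(Cy5/Cy3) of 8 positive controls, 48 spots each, on the 3 arrays (symbols). Replicate 2 lies on the other side of 0 from replicates 1 and 3 for all 8 controls, as for Y6 with -4.01, 4.84 and -4.38 on replicates 1, 2 and 3.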

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

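All tests weighed in this part were chosen after the results they bear on had been seen. The positive controls Y1 to Y8, which no comparison used, gave a signal on every array. Their mean log2(phoxim/control) was -1.98 for Y1, -2.27 for Y2, -1.98 for Y3, -2.37 for Y4, 0.86 for Y5, -4.35 for Y6, -1.19 for Y7 and -3.19 for Y8. Negative control spots of 50%DMSO, also unused, had median Cy3 intensities of 73, 205 and 133 on replicates 1, 2 and 3, while blank spots had 1, 0 and 0.

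The controls bear on the direction of replicate 2, for which labels and header name opposite dyes. The sign of Cy5 over Cy3 was opposite on replicate 2 for 8 of the 8 controls, which argues against the labels' statement that no dye was swapped. This holds if each control mix went with the same kind of RNA on every array, which the sources used here do not state. No biological explanation was tested for this pattern.

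The higher storage and 30K proteins may have technical sources. Their median log2 ratio on replicate 2, with the dyes the other way, was 1.62 (95% bootstrap interval 0.85 to 2.16, 14 genes), so it did not reverse with the dyes. This is no independent test of a dye effect, because the families were grouped after their values were seen. Of the 14 genes 9 had been called, and every called probe had 1 sign on all arrays. The interval covers the spread over genes on 1 array, not that between pools. Fat body carried over with the phoxim midguts cannot be told apart from a change within the midgut. The 16 other genes listed as fat body or haemolymph, 3 of whose ratios had been seen before, had a median of 0.076. The set held genes such as Spi2, a silk proteinase inhibitor, whose expression in fat body was not tested. At a median control intensity of 1412 a midgut level of their own could also hide a rise in these 16 genes. The storage and 30K genes had a similar median control intensity of 1437, with a median log2 ratio of 2.09. Unequal fat body between dissected pools stays open too. Between the control RNAs of replicates 3 and 1, 8 of the 14 genes lay above the 95th percentile of all kept probes (0.67 on the log2 scale) and 6 within the central 90%. Their median of 1.33 lay above 98.9% of single probes, a test that is void because it sets a median against single probes. The phoxim RNAs differed alike, with a median of 1.60, so this is a difference between replicates and decides nothing within a pair. A response of the midgut itself to phoxim also stays open.

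Replicates 1 and 2 shared changes that replicate 3 lacked. Among the kept probes a dye effect is argued against. Replicates 1 and 2 have opposite dyes, and their correlation exceeded that of replicates 1 and 3, which share dyes, by 0.44 (95% bootstrap interval 0.37 to 0.49, over probes and not arrays). Over all gene probes, most of them dim, the correlations did follow the dyes. There r was -0.47 for replicates 1 and 2, 0.42 for 1 and 3 and -0.45 for 2 and 3. The authors' normalization is argued against as the whole source, because loess on the deposited intensities left the difference among kept probes at 0.25 (0.19 to 0.31). A difference between the larval pools was not tested and stays open.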

How the results depend on the processing

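Alternatives not named in the plan were chosen after seeing the data: the additions of 50 or 10 with loess, loess within blocks, the dye term, the turned replicate 2, the level of 1500, the members left out, the mitochondrial ribosomal proteins left out and the array's gene models. Where no cause is named, the cause was not tested. Normexp could not be fitted to the deposited intensities, which are already subtracted; the version without subtraction was not run because no separate background was used here, and the intensity trend was not run for gene lists. Aquantile leaves ratios as loess with 50 added gives them. No paired analysis was possible because each array already holds 1 treated and 1 control RNA and there is 1 group of arrays. Dim signal limited the comparison: 3964 of 23229 probes were above the flag level on all arrays.

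The count of called probes was 27, with 20 higher and 7 lower. It was 34 with plain subtraction and loess, 31 with 50 added and loess, 23 with 10 added, 22 with loess within blocks and 28 with the intensity trend. With median centring 18 were called, 4 of them lower. With scaling between arrays 1 was called, 1 higher and 0 lower, with 600 at an unadjusted p below 0.05 against 603 in the main setting. With all probes kept 0 were called, 0 higher and 0 lower, in limma, with 450 at an unadjusted p below 0.05 among 23229 tested. With both channels above the flag level 16 were called, 2 of them lower, among 3215 tested, and with the level of 1500 17 were called, 2 of them lower, among 1589. The test against 1.5-fold called 9, 6 higher and 3 lower. With the dye term 0 were called, 0 higher and 0 lower, in limma, with 348 at an unadjusted p below 0.05; the term takes 1 of the 2 residual degrees of freedom. With replicate 2 turned 0 were called, 0 higher and 0 lower, with 29 at an unadjusted p below 0.05. Leaving out 1 replicate gave 4 to 470 called, 4 to 283 higher and 0 to 187 lower. The lowest counts came without replicate 2 and the highest without replicate 3, and the cause was not tested.

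The number of called lists was 7. It was 10 with 50 added and loess, 9 with plain subtraction, and 8 with median centring, 10 added, loess within blocks, both channels above the flag level or members left out. It was 7 with scaling between arrays, the mean of all probes of a gene or 3 mitochondrial ribosomal proteins left out, where the ribosomal mean was -0.053. It was 6 with the dye term or the array's gene models, 5 with the level of 1500 among 18 tested, 2 with all probes kept or replicate 2 turned and 0 with an estimated correlation. It was 5 to 7 when 1 replicate was left out. Of lists not called, cytochrome P450, peritrophic membrane and chitin, and V-ATPase genes passed with 50 added and with plain subtraction, and in 3 to 5 further settings each; cuticle and tracheal genes passed without replicate 3. With an estimated correlation the means stayed, and the call was lost, for fat body (1.12), muscle (0.53), haemocyte (0.56), UDP-glycosyltransferase (0.84), serine protease (0.23), oxidative phosphorylation (-0.11) and ribosomal protein (-0.061) lists. Under the other alternatives the fat body and muscle lists passed each time, with means of 0.55 and 0.32 when replicate 2 was turned; the fat body mean was 0.72 with all probes kept and 1.66 with members left out. The oxidative phosphorylation mean was -0.24 with plain subtraction, -0.23 with 50 or 10 added, -0.21 with loess within blocks and -0.044 with median centring. The ribosomal mean was -0.21, -0.19, -0.19 and -0.0042 in these settings. The serine protease list did not pass with plain subtraction (0.10), median centring (0.30), all probes kept (0.10), 10 added (0.12), loess within blocks (0.12), the dye term (0.20) or replicate 2 turned (0.16). With all probes kept the UDP-glycosyltransferase (0.14), ribosomal (-0.012), oxidative phosphorylation (-0.091) and haemocyte (0.16) lists did not pass. The haemocyte list did not pass with both channels above the flag level (0.17) or the array's gene models (0.48). With replicate 2 turned the UDP-glycosyltransferase (0.18), haemocyte (0.19) and oxidative phosphorylation (0.00294) lists did not pass, and the ribosomal list changed sign (0.033). Leaving out 1 replicate gave means of 0.14 to 0.30 for serine proteases (lost without replicate 1 or 3), 0.60 to 1.16 for UDP-glycosyltransferases and 0.50 to 0.63 for haemocyte genes (both lost without replicate 3). It gave -0.13 to -0.021 for ribosomal proteins (lost without replicate 2 or 3) and -0.15 to -0.081 for oxidative phosphorylation (lost without replicate 2).

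Of the 17 named genes that passed, 17 also passed with the intensity trend and with the mean of all probes of a gene, and 16 with plain subtraction. With scaling between arrays 1 passed, the 17 all having an adjusted p of at most 0.061, and with replicate 2 turned, the dye term or all probes kept 0 passed. No named gene past the threshold changed direction in any setting run.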

Other observations

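The test in this part was chosen after the counts had been seen. An array-wise change of sign gives 4 patterns of the 3 arrays, too few for a share under 0.05. The real directions, 1 of the 4, gave 27 called probes, and the highest of the other patterns gave 0.

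Pathway terms that the files attach to probes, tested with camera after the data had been seen, gave 1 of 92 terms past the threshold. It was oxidative phosphorylation, with a mean log2 ratio of -0.13 over 52 genes (adjusted p = 0.037, camera, or adjusted p = 0.80 with an estimated correlation). Its medians were -0.25, -0.14 and 0.0034 on replicates 1, 2 and 3. The term covers the same pathway on the same arrays as the oxidative phosphorylation list above, so it is no independent result.

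Of the heat shock proteins, Hsp20.8 had log2 ratios of 0.97, 0.57 and 2.29 on replicates 1, 2 and 3, and Hsp90 had 0.37, 0.50 and 0.35 (adjusted p = 0.14 and 0.29, limma). Of the hormone genes, the 3-dehydroecdysone reductase probes sw22643 and sw22644 had means of -1.04 and -1.10 (adjusted p = 0.11 and 0.13, limma), lower on 3 of 3 arrays. These genes were named after their values were seen.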
